A study of Paracoccus denitrificans with 2 samples.

How the data were processed

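RNA was measured in 2 libraries of the denitrifying bacterium Paracoccus denitrificans, 1 per condition. Per the labels' protocols, cells were grown with oxygen in a rich broth, harvested, and placed in minimal medium with 1000 µg/L hexavalent chromium, Cr(VI). The anoxic library came from reactor 1, sampled after 5 h of exposure with nitrate, and the aerobic library came from reactor 5, sampled after 5 h of aerobic exposure. The label of the aerobic reactor does not mention nitrate. Per the labels' protocols, ribosomal RNA was removed from total RNA and strand-specific paired-end libraries were sequenced on an Illumina instrument.

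The submitters' processing notes name cutadapt 1.10, FastQC 0.10.1, Bowtie2 2.2.0, StringTie 1.3 and edgeR. Their settings, the treatment of reads that fit several places, the use of strand in counting and the genome build are not given in the sources used here. The values used were the FPKM (fragments per kilobase per 1000000 mapped) as deposited and the estimated count per gene as deposited, both per the file headers. In all 3794 genes of the anoxic library and in 3793 of the aerobic library, the deposited estimated count equalled the FPKM times gene length times 1 constant, rounded up, within 0.01 counts. The count columns are therefore coverage estimates and not tallies of whole reads. The constants were 55828385 and 44580559, of which all 3794 genes together hold 95.2% and 95.0%. The remainder was not analysed here. The estimated counts summed to 53147814 in the anoxic library and 42337039 in the aerobic library, and 35 and 45 genes stood at 0. Symbols, descriptions and positions were taken from the same deposited table. 755 genes carry a symbol and 47 have no description. Other genes are given by their identifiers.

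The measure was the log2 ratio, anoxic over aerobic, of FPKM plus a pseudocount of 1, which understates the difference of genes with low values. Genes needed an FPKM of at least 5 in 1 of the libraries, which kept 3317 genes and left out 474. The 3 genes with the symbol of 5S ribosomal RNA were also left out. Genes were called higher or lower at a 2-fold difference. With 1 library per condition there is no replicate check, so no p-value or standard error was computed between conditions, and all differences describe these libraries. Folds of named genes carry 95% conditional Poisson intervals (Clopper-Pearson) computed from the estimated counts and scaled by the constants above. They are approximate, because the counts are coverage estimates, and cover counting error only.

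40 gene lists, defined by symbols and by words in the descriptions, and a pooled denitrification list were fixed before the data were examined. The handling of capital letters in descriptions was settled after list members had been seen: the case of the first letter of each word was ignored. A list with at least 3 measured members received the percentile of its median among 10000 random lists of the same size, matched on deciles of mean expression. A list was said to stand apart below a percentile of 2.5 or above 97.5. 39 lists had a percentile. The random lists draw scattered genes, whereas several lists hold neighbouring genes that differ together and some lists share members, so the percentiles describe these libraries and are not chance levels. The named genes were the 12 with the highest and the 12 with the lowest ratio among genes with an FPKM of at least 50 in the higher library and a symbol or an informative description. For each list up to 6 members with the highest mean FPKM could be named, as could both chrA genes and the 10 most abundant genes of each library. Genes outside this rule are marked as chosen after their values were seen.

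Genes that share at least 1 base with another gene of the table numbered 1489, or 39.2%. Their values are uncertain because coverage estimates can assign shared stretches to either gene, and the same holds for near-identical copies.

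The procedure was tested on simulated counts drawn for the same genes at the same depths. For this comparison, 100 of 100 genes set 3-fold apart and 100 of 100 set 6-fold apart passed the 2-fold threshold in the right direction, against 0 of 3103 unaltered genes, and the intervals covered the true fold in 95.3% of 3303 genes. The simulation held only counting error, the error that the intervals assume, with no biological spread and no uncertainty from overlapping genes. It therefore checks the calculation and not the real differences. Alternatives changed the pseudocount to 0.1 and 5, the scaling, the FPKM floor, the threshold, and the matching and summary of the lists. Others, which left out overlapping genes, asked for an FPKM of at least 5 in both libraries or ignored all letter case, were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.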

Results

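The transcripts of P. denitrificans, a soil bacterium able to respire nitrate in place of oxygen, were measured after 5 h with 1000 µg/L Cr(VI), either without oxygen and with nitrate or under aerobic conditions. Each condition had 1 library, so no difference below could be set against a spread between replicates. All 3794 genes together, before any were left out, held 53147814 estimated counts in the anoxic library and 42337039 in the aerobic library, with a median of 3461 and 2481 per gene. The 10 most abundant genes held 15.7% of counts in the anoxic library and 22.2% in the aerobic library. The most abundant was ssrA, the transfer-messenger RNA that rescues stalled ribosomes, with 2.72% and 5.22% of counts.

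The comparison asks how gene expression under chromate differs between respiration with nitrate and with oxygen. Within denitrification, the stepwise reduction of nitrate to dinitrogen, the steps went in opposite directions. Genes of nitrite and nitric oxide reduction were higher in the anoxic library: nitrite reductase (PDEN_RS12360) stood at 7107 against 776 FPKM, 9.16-fold higher, and nitric oxide reductase (PDEN_RS12340) at 3967 against 206 FPKM, 19.2-fold higher (95% counting interval 18.9 to 19.6). Genes of the membrane-bound nitrate reductase, which starts the pathway, were lower: narH, its beta subunit, stood at 136 against 1161 FPKM, 8.53-fold lower in the anoxic library (95% counting interval 8.36 to 8.70). nosZ, the nitrous oxide reductase that ends the pathway, stood at 7208 against 15677 FPKM, a log2 ratio of -1.12.

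The median log2 ratio of the 3317 genes was 0.13, and list medians are given relative to this value. All 4 measured nar genes were at least 2-fold lower in the anoxic library, with a median of -2.93, below the medians of all 10000 matched random lists. They lie side by side on chromosome 2, with NarK family nitrate/nitrite transporter PDEN_RS21110 (452 against 1785 FPKM), chosen after its values were seen. The nir list had a median of 3.07 (percentile 99.98): 2 of its 3 members were at least 2-fold higher, and nirD was at 48.9 against 52.0 FPKM. nirD, described as a nitrite reductase small subunit, entered the list by its name, and whether it takes part in denitrification was not checked. Without nirD the nir list would fall below 3 measured members and have no percentile. Both measured nor genes were higher, at log2 ratios of 4.26 and 4.36. In the nos list 3 of 5 members were at least 2-fold lower and the median was -1.19 (percentile 0.16), while the regulatory gene NosR (PDEN_RS21025) stood at 1504 against 1571 FPKM. Of the 3 lower members, the NosL family gene PDEN_RS21000 was at only 14.8 against 33.1 FPKM and overlaps another gene, so its value is uncertain. The 3 measured genes of the periplasmic nitrate reductase were within 2-fold, with napA at 585 against 611 FPKM. Pooled, 4 of the 17 genes in these lists were at least 2-fold higher, 7 lower and 6 within 2-fold, and the pooled median of -0.25 did not stand apart (percentile 7.76). This call depended on the members: before centring the pooled median was -0.12, against 1.34 without overlapping genes, where the list stood apart high (percentile 100), and -1.06 with symbols only, where it stood apart low (percentile 0). It depended on the matching too, as the same members stood apart low against unmatched random lists (percentile 0.96). Members were found by symbols and descriptions, so the pooled counts leave out nirF and other genes that lie beside the nir and nor genes. They also leave out genes beside the nos genes on the same strand. Of these, chosen after their values were seen, PDEN_RS20995 (606 against 709 FPKM), PDEN_RS21010 (789 against 1145) and PDEN_RS21030 (690 against 842) were within 2-fold.

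**Figure D1:**
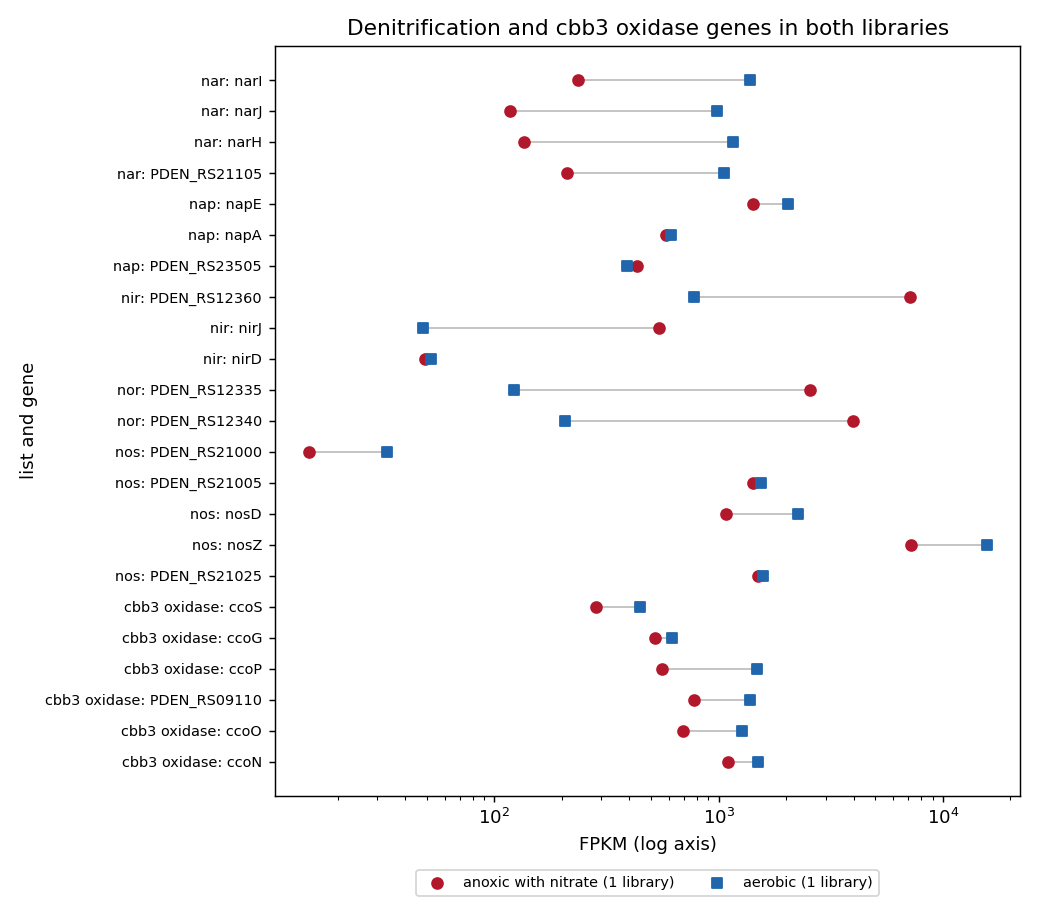
FPKM on a log axis of each measured member of the nar, nap, nir, nor, nos and cbb3 oxidase lists, with circles for the anoxic library with nitrate and squares for the aerobic library, 1 library each. The nor genes and 2 of the 3 nir genes lie to the right in the anoxic library, and all 4 nar genes lie to the left.

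Both nor genes and 2 of the 3 nir genes, all but nirD, lie in 1 region of chromosome 1, from 2496242 to 2512991, in the coordinates of the deposited table. The edges of this region were chosen after the values were seen and lie at genes that were at least 2-fold higher, so the share of higher genes within it is partly set by that choice. Of its 16 genes, 15 were at least 2-fold higher in the anoxic library, by 3.41-fold to 20.7-fold. Named among them were cobA, a methyltransferase of tetrapyrrole synthesis, 16.9-fold higher, nirF (PDEN_RS12375), 14.7-fold higher, and PDEN_RS12335, described as a CbbQ/NirQ/NorQ family protein, 20.7-fold higher. The exception, PDEN_RS12350, was near 0 in the anoxic library (0.567 against 79.3 FPKM) and overlaps its neighbour PDEN_RS12355 by 4 bases. This neighbour, the gene at 3.41-fold (119 against 34.9 FPKM), gained 210% of the coverage missing from PDEN_RS12350. Coverage may thus have been assigned differently between them, and the direction of both is uncertain. Pseudoazurin PDEN_RS21035, a copper protein that carries electrons to nitrite reductase, lies on chromosome 2 and was 17.5-fold higher, at 3390 against 194 FPKM.

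**Figure D2:**
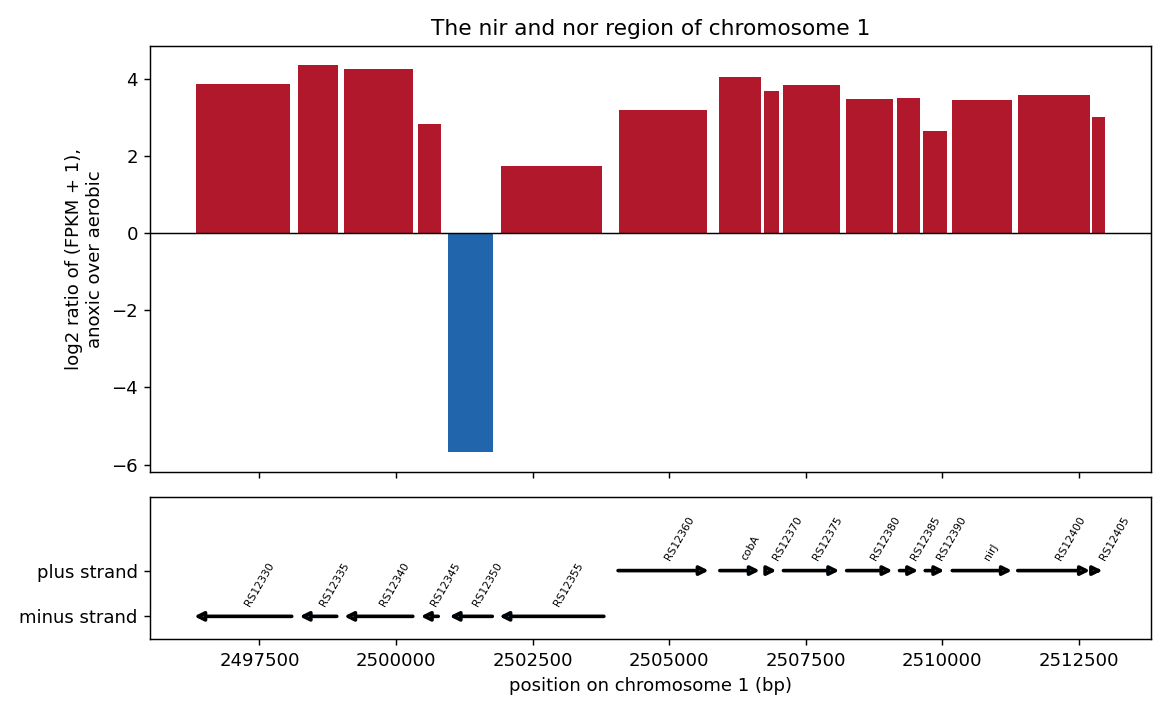
Log2 ratio of FPKM plus 1, anoxic over aerobic, for the 16 genes from 2496242 to 2512991 of chromosome 1, with bars as wide as the genes and arrows showing their strand. Bars of 15 genes lie above 0, and that of PDEN_RS12350, which overlaps its neighbour, lies below.

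Outside that region, 2 of the 3 measured nitric oxide detoxification genes were at least 2-fold higher in the anoxic library. hmpA, a flavohaemoprotein that detoxifies nitric oxide, was at 137 against 17.4 FPKM, 7.87-fold higher, and ric, for the repair of iron-sulfur clusters, at 1434 against 141 FPKM, 10.2-fold higher. The list had a median of 2.78 (percentile 99.995), and its other member, the hybrid-cluster oxidoreductase PDEN_RS05885, stood at 55.3 against 76.9 FPKM. Without the FPKM floor this list no longer stood apart (percentile 80.1). The 8 measured genes of the list of FNR family regulators, which also holds NnrU and NnrS family genes, were all within 2-fold, and their list did not stand apart (percentile 26.8).

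Terminal oxidases divided. The cbb3 oxidase list, an enzyme with high affinity for oxygen, had a median of -0.88 (percentile 0.35), with 1 of 6 members at least 2-fold lower and the others within 2-fold. The quinol oxidase list had a median of 0.83 (percentile 99.97), with cyoC 2.91-fold and cyoB 2.44-fold higher in the anoxic library and 2 further members within 2-fold. The aa3 oxidase list did not stand apart (percentile 97.35). Cytochrome-c peroxidase PDEN_RS04435, which reduces hydrogen peroxide, was at 7771 against 21496 FPKM, 2.77-fold lower in the anoxic library, while the 12 other measured oxidative stress genes were within 2-fold and the list did not stand apart (percentile 20.6).

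The 2 chrA genes, for chromate transporters, were higher in the anoxic library. The copies on chromosome 2 have the same length of 1365 bp, may share reads, and each overlap a neighbour, so their single values are uncertain: they stood at 61.1 against 9.61 FPKM and at 63.7 against 8.88 FPKM. Summed, they were 6.75-fold higher (95% counting interval 6.34 to 7.18). The sum does not remove the uncertainty from the overlaps. If shared reads were credited to both copies, the interval is too narrow. The list of flavoproteins related to chromate reduction had 9 measured members, all within 2-fold, and did not stand apart (percentile 59.7). The list of sulfate uptake and cysteine synthesis, whose transporters also carry chromate, had a median of 0.27 (percentile 99.5) with 4 of 23 members at least 2-fold higher and none at least 2-fold lower. These 4, chosen after their values were seen, were PDEN_RS03255 (described as a nitrite/sulfite reductase, 132 against 35.8 FPKM), PDEN_RS03260 (phosphoadenylyl-sulfate reductase, 270 against 87.9 FPKM), cysA (232 against 96.4 FPKM) and PDEN_RS08870 (sulfate-binding protein, 214 against 77.4 FPKM). Without overlapping genes the sulfate list no longer stood apart (percentile 93.9).

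Ribosomal protein genes were lower in the anoxic library as a list, with a median of -0.55 that lay below the medians of all 10000 random lists. 49 of 53 had a ratio below 0, though 48 were within 2-fold, and rpsU stood at 1815 against 3285 FPKM. Mobile elements also had a low median of -0.22 (percentile 0.645), with 1 of 27 members at least 2-fold lower, and did not stand apart without the FPKM floor (percentile 4.31) or by the mean (percentile 9.56). Lists with a high median and most members within 2-fold were ATP synthase (0.34, percentile 98.2), the tricarboxylic acid cycle (0.20, percentile 98.5), nitrogen assimilation (0.27, percentile 97.8), chaperones and heat shock proteases (0.12, percentile 99.3) and cytochrome bc1 with its electron carriers (0.35, percentile 97.52), and each of these lost its place under at least 1 alternative. In nitrogen assimilation, glnA, glutamine synthetase, was 2.89-fold higher and the regulator PDEN_RS22225 of the P-II family 2.81-fold higher. DNA repair and SOS genes showed little difference: all 43 were within 2-fold, with the list at percentile 41.5. In all, 14 of 39 lists stood apart, 9 with high and 5 with low medians. Without overlapping genes the nar, nir, nos and quinol oxidase lists fell below 3 members and could not be placed.

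**Figure D3:**
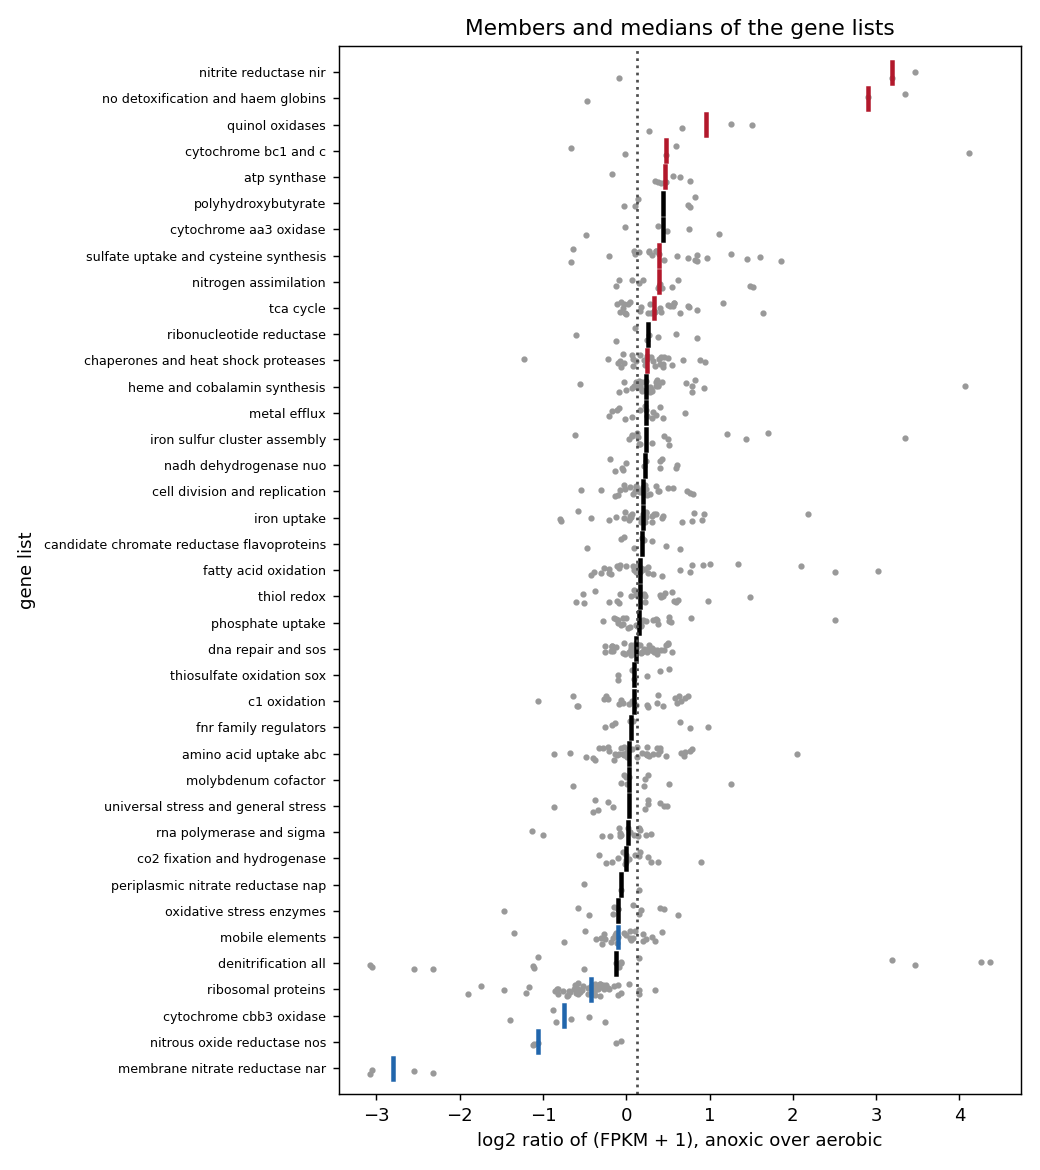
Log2 ratios of FPKM plus 1, anoxic over aerobic, for the members (grey points) of the 39 lists with at least 3 measured members, and their medians (bars, red where the list stood apart with a high median, blue with a low one). The dotted line is the median of all genes, 0.13; nir and nar lie at opposite ends.

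Across the genome 113 genes were at least 2-fold higher in the anoxic library and 106 lower, and 3098 (93.4%) were within 2-fold. Among the named genes lower in the anoxic library, 5 lie close together on plasmid 1, among them a subunit of acetoin dehydrogenase, an enzyme of acetoin breakdown. This subunit, PDEN_RS24780, stood at 39.8 against 699 FPKM, 17.5-fold lower (95% counting interval 16.8 to 18.3), and PDEN_RS24785 at 50.9 against 664 FPKM. 8 of the 24 named genes were below 3 FPKM in 1 library, and all 8 overlap another gene. They include a metallophosphoesterase, PDEN_RS11820 (217 against 0.241 FPKM), and an ABC transporter subunit, PDEN_RS02625 (0.232 against 99.1 FPKM). The share of higher calls, 51.6%, moved with the scaling: it was 67.2% with each library rescaled to the same FPKM sum, and 44.2% (99 higher, 125 lower) with ratios centred on their median. Leaving out overlapping genes gave 59 higher and 75 lower genes.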

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

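The test of gene length was set out before its result was seen, and the other tests in this part were chosen after theirs. The 3 genes with the symbol of 5S ribosomal RNA, which the comparisons leave out, drew attention because they held signal above the 3 counts that a count of 0 allows: their estimated counts summed to 804 in the anoxic library and 1351 in the aerobic library. These sums are not scaled for depth. In FPKM the genes summed to 125 in the anoxic library and 263 in the aerobic library. Their description in the table is that of a hypothetical protein.

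Ribosomal protein genes were lower in the anoxic library too, with a median of -0.55 relative to all genes. A bias against short genes does not account for this: against random lists matched on both length and expression the list lay at percentile 0. Its median log2 ratio before centring was -0.43, against 0.06 for 550 other genes of 273 to 516 bp. Slower growth without oxygen may contribute and stays open: the list of cell division and replication stood at percentile 73.4 and that of RNA polymerase and sigma factors at percentile 24.3, neither standing apart, and with 1 library per condition growth cannot be told apart from the reactor.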

How the results depend on the processing

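No paired analysis was possible because each condition has 1 library. The authors' own fold changes, which had been listed among the alternatives, were not run because the table analysed holds none. Count ratios differ from FPKM ratios by about 1 factor, so a ratio of counts scaled to library totals tests little. Leaving out overlapping genes, an FPKM of at least 5 in both libraries and ignoring all letter case were chosen after seeing the data. All 24 named genes stayed at least 2-fold apart in the same direction under the pseudocount and scaling alternatives. This tests little, because these genes were picked for the largest ratios at an FPKM of at least 50. Among list values, 461 of 491 kept their place. Part of that agreement is built in, since centring shifts every ratio equally and cannot change a percentile. Depth leaves wide intervals for genes near 0: with 9 estimated counts in the aerobic library, the fold of PDEN_RS11820 has a counting interval of 446 to 1854.

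Of 219 genes at least 2-fold different, 65 passed 4-fold (40 higher, 25 lower). Without overlapping genes, where fewer genes enter, 134 remained: 59 of 113 higher and 75 of 106 lower. The share of higher calls was then 44.0%, against 51.6%, and why higher calls fell more was not tested. 14 lists stood apart, against 7 without overlapping genes and 6 with symbols only, each total with 1 added list. Of the 14, 4 and 6 fell below 3 members and could not be placed, and 4 and 3 lost their place. For the following medians the cause was not tested. They are not relative to the median of all genes and cannot be set against the centred medians given earlier. The denitrification median of -0.12, which did not stand apart, turned to 1.34 and stood apart high without overlapping genes, and stood apart low at -0.12 against unmatched lists and at -1.06 with symbols only. Cytochrome bc1 lost its place with a pseudocount of 0.1 (0.48), a trimmed mean factor (0.35), no floor (0.23), no overlapping genes (0.48) and unmatched lists (0.48). Nitrogen assimilation lost it with no floor (0.29), a floor of 20 (0.39), no overlapping genes (0.40), symbols only (0.62) and means (0.46). With no floor, nitric oxide detoxification (0.19) and mobile elements (-0.029) lost theirs, and metal efflux (0.24) and carbon dioxide fixation with hydrogenase (-5.75e-05) gained one. Without overlapping genes, ATP synthase (0.47) and sulfate uptake (0.31) lost theirs. With unmatched lists chaperones (0.25), and with symbols only the tricarboxylic acid cycle (0.35) and chaperones (0.24), lost theirs. With means, ATP synthase (0.43), the tricarboxylic acid cycle (0.38), chaperones (0.22) and mobile elements (-0.11) lost theirs, and iron-sulfur cluster assembly (0.60), haem and cobalamin synthesis (0.39) and fatty acid oxidation (0.41) gained one. With an FPKM of at least 5 in both libraries, aa3 oxidase (0.44) gained one.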

Other observations

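All tests in this part were chosen after the results were seen. Neighbouring genes often differed together. Runs of at least 3 adjacent genes on 1 strand, all at least 2-fold apart in the same direction, numbered 17 and held 77 genes, against at most 2 runs in 1000 shuffles of gene order within replicons. Higher in the anoxic library were 4 genes of lactate use on chromosome 2 (85916 to 90527, log2 ratios 1.76 to 2.92), 6 genes from glpK, glycerol kinase, through a glycerol-3-phosphate transporter (1579716 to 1586290, 1.03 to 2.51), and 5 genes that include an acyl-CoA dehydrogenase and a 3-hydroxyacyl-CoA dehydrogenase (32696 to 39209, 1.02 to 3.03).

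Lower in the anoxic library were 7 genes of the acetoin group on plasmid 1 (491175 to 497568, log2 ratios -4.10 to -2.40), 4 genes there with paaA and paaC of phenylacetate breakdown (304007 to 307388, -1.27 to -1.12), 3 genes of acetone carboxylation on chromosome 2 (1429004 to 1434062, -2.54 to -1.09), and 2 runs of 4 genes on chromosome 1 with tssF, tssG, tssJ, tssK and tssM of type VI secretion, an apparatus that injects proteins into other cells (from 2451018 to 2463124, -2.31 to -1.08). A further 3 runs of 3 genes each span 3381 bp. Their sequences were not compared, and reads shared between copies would leave their values uncertain.

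12 genes were below 3 FPKM in 1 library and at 20 FPKM or more in the other, 6 in each direction. Transcription of a whole stretch, neighbours included, in 1 library alone is argued against by the overlapping neighbours on the same strand, whose median log2 ratio in the direction of the gene was -0.11. These neighbours overlap as well, so their own values are uncertain, and a difference in the gene alone is not tested by them. The 2 of 16 neighbours that were at least 2-fold apart the same way are PDEN_RS06355 and PDEN_RS06360, each other's neighbour, so for this pair a joint difference stays open. A coverage estimate lost where genes overlap is a candidate explanation that stays open. Among the 12 genes, 91.7% overlap another, against 38.0% of 3006 other genes at this level (Fisher's exact test across genes, two-sided, p = 0.000192). The listed overlaps, however, span only 1 or 4 bases. Overlapping genes were under 1 FPKM in both libraries no more often than others (6.98% against 8.77%). This rate cannot decide the question, because it may also count genes not transcribed in either library. Single overlapping genes, chosen after their values were seen, were near 0 in both libraries while a gene with a neighbouring identifier was expressed. rplV stood at 0.287 against 0.615 FPKM and rpsC at 466 against 595, PDEN_RS11180 at 0.708 against 0.646 and ndhC at 812 against 537. Coverage of overlapping genes given to a neighbour also stays open, for part of the 12 genes at most. The neighbours of 2 of the 11 that overlap gained at least 50% of the missing coverage, with a median of 10.1%.

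The steps of denitrification went in opposite directions, and the nar, nos and cbb3 oxidase lists and cytochrome-c peroxidase were higher in the library labelled aerobic, against what is known of their induction when oxygen runs short. Labels of the libraries exchanged would put 3 of the 5 nar, nir, nor, nos and cbb3 lists higher in the anoxic library, in place of the 2 that are higher as labelled. Neither assignment places all 5 there, so whether the labels are right stays open, and all directions given are those of the libraries as labelled. Overlap does not account for the opposite directions of the 4 nar, nir and nor members that overlap no other gene. Of these, 100% were past 2-fold in the direction of their list: narI lower (236 against 1381 FPKM), and PDEN_RS12360 and both nor genes higher. These genes help set the direction of their lists, and narI is the only nar gene among them. How far overlap shaped the lists as a whole is therefore not settled. A hypothesis that no test here decides is that nir and nor follow nitric oxide while nar and the cbb3 oxidase follow oxygen. The nitric oxide detoxification list lay at 2.78 relative to all genes, but this rests on 2 of 3 measured genes, and without the FPKM floor the list had a median log2 ratio of 0.19 (percentile 80.1). The hypothesis needs nar and the cbb3 oxidase to follow oxygen in a direction opposite to that known induction, unless oxygen was short in the aerobic reactor, which was not measured here. Oxygen supply and reactor differ together, and whether nitrate differed is not stated in the labels, so these cannot be told apart.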
